A study of Mus musculus with 12 samples.

How the data were processed

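Gene expression was measured by RNA sequencing in 12 libraries of sorted mouse epithelial cells. Per the labels' protocols, gallbladder and proximal small intestine of Flare25 reporter mice were dissociated with EDTA and DTT, and live single EpCAM+ cells were sorted by red fluorescence into IL-25+ and IL-25- fractions. Per the labels' protocols, mRNA was captured on beads, cDNA was amplified with a NuGen kit, libraries were made with Nextera XT, which does not mark strand, and single-end 50 bp reads were run on a HiSeq instrument. The deposited table holds raw read counts per Ensembl gene, which per the submitters' processing notes came from STAR 2.7.2b alignment to GRCm38. The notes also list DESeq2 1.26, and they name no read counter, strand setting or annotation release. The table held 43432 genes, of which 42462 were matched to a symbol and position in GENCODE M21 for GRCm38 and 970 were not, and the unmatched genes held at most 0.132% of the counts of any library. A further 11 columns of the table match no sample label and were not used.

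Libraries were grouped by tissue and sort gate as the labels give them, 3 per group in 4 groups. Totals ran from 23703449 to 64736650 counts. A count of 0 allows up to 3 counts, which corresponds to 0.0421 CPM in GB-neg 1 up to 0.1216 CPM in SI-pos 3 and to 0.0221 to 0.0394 CPM over a group of 3 libraries. Replicate libraries were checked to be distinct, with a chi-square per degree of freedom of at least 49.16 for each pair.

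Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 16636 genes. Library sizes were scaled by TMM, dispersions were estimated over all 12 libraries with the group as the only factor, and a robust quasi-likelihood model was fitted. Tests were two-sided quasi-likelihood F tests, with Benjamini-Hochberg adjustment per comparison, a threshold of 0.05 and no cutoff on fold change. The standard error of a log2 fold change is its size divided by the square root of F. The comparisons were IL-25+ against IL-25- in each tissue, gallbladder against small intestine in each gate, and the interaction of tissue and gate. Genes called in the same direction in both tissues were counted beside the overlap of independent calls.

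The 26 gene lists were written from general knowledge of cell types and pathways. They cover tuft identity, taste transduction, tuft effector and eicosanoid, luminal metabolite receptors, tuft-1 neuronal-type, tuft-2 immune-type, bile acid and biliary transport, and gallbladder and cholangiocyte identity. They also cover enterocyte, intestinal transcription factors, goblet, Paneth, enteroendocrine, stem, proliferation, T cell and intraepithelial lymphocyte, B and plasma cell, myeloid, and stroma and endothelium. The remaining ones are hepatocyte, pancreatic acinar, MHC class II, interferon response, neutrophil chemokine and antimicrobial, dissociation stress, and mitochondrially encoded genes. Of 14 genes written in the T cell list, 13 were in the table. Lists with at least 3 tested members, 24 in all, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run as checks. Counts of members are given over all genes tested and adjusted over the list alone.

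The samples, comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes Il25, the 6 largest fitted increases and decreases per comparison among called genes with at least 10 CPM in the higher group and groups that do not overlap, the 4 members of each list with the lowest adjusted p, members called against their list's majority, and the receptors Sucnr1 and Gpbar1. The text gives the first, second and last kinds in full. Of list members it gives those whose calls held under each alternative, except for 1 left out, and those called against the majority with their limits. Folds against a group at 0 counts use a floor of 3 counts over the group, and ratios against 1 to 3 counts carry exact binomial 95% intervals.

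Alternatives were RLE size factors, DESeq2 1.42.0, limma-voom with quality weights, no filter on low counts, a stricter filter (5 CPM in 3 libraries), the replicate number as a block, the block nested in tissue, a fit of the compared groups alone, and leaving out each library. Leaving out the pair of libraries that share transcripts, the pair of gallbladder libraries numbered 2, or the mitochondrial genes was added after the data had been seen. The procedure was tested on simulated counts in which randomly drawn genes were changed by 2, 4, 8 or 16-fold. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

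Some values are uncertain for technical reasons. Reads without strand cannot separate genes that overlap on opposite strands, and 50 bp reads can be split between close paralogs, such as Mx1 and Mx2, Reg3b and Reg3g, the Defa genes, Apol9b and its neighbours, and the class I genes. Of 184 genes with a result in the text, 5 had more than 25% of their exon bases covered by another gene, namely Cd72, Itgam, Kctd12, Serpina1c and Trf. Folds against a group with 0 to 3 counts were, after the data had been seen, also computed without each library of the higher group, and beside a printed fold the text gives the lowest where it is more than 1.5 times smaller. It also gives fitted changes that lost over 1 log2 unit without a library. The mitochondrial genes mt-Co2, mt-Co3 and mt-Atp6 hold at most 3 counts in any library of the deposited table and were not tested.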

Results

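Bulk RNA sequencing profiled epithelial cells sorted from Flare25 mice, a reporter strain in which cells that transcribe Il25 carry a red fluorescent protein. In gut epithelium IL-25 comes mainly from tuft cells, rare chemosensory cells that signal to type 2 immune cells. Live single EpCAM+ cells from the proximal small intestine and the gallbladder were sorted into IL-25+ and IL-25- fractions, which gave 4 groups of 3 libraries. Libraries are named here by tissue, gate and replicate number, so that SI-pos 1 is the first small intestine IL-25+ library and GB-neg 3 the last gallbladder IL-25- library. Read counts summed to 29662253, 29709243 and 28546273 in SI-pos 1 to 3, and to 32775889, 36785509 and 37760914 in SI-neg 1 to 3. They summed to 28373985, 23703449 and 30957874 in GB-pos 1 to 3, and to 64736650, 31022526 and 34921443 in GB-neg 1 to 3.

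The labels list a dye-coupled house dust mite allergen, given 1 day before collection, for the 6 gallbladder libraries and for no small intestine library. The protocol field of all 12 libraries says homeostasis. Each comparison between tissues is therefore also a comparison across that label. Mitochondrially encoded transcripts took 17.2, 17.2 and 12.1% of counts in SI-pos 1 to 3 and 26.6, 34.9 and 27.1% in SI-neg 1 to 3. They took 7.14, 8.66 and 8.83% in GB-pos 1 to 3 and 11.2, 14.2 and 25% in GB-neg 1 to 3. GB-neg 1 held intestinal transcripts: 23 abundant enterocyte genes reached a median of 5.48% of their SI-neg 3 level there, and at most 0.328% in each of the other 5 gallbladder libraries. SI-neg 3 in turn held gallbladder transcripts, with a median of 1.83% of the GB-neg 1 level over 58 genes.

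In what follows, values are CPM (read counts scaled by library size) as mean ± SD and log2 fold changes as estimate ± SE, each with n = 3 libraries per group. Adjusted p values come from edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment unless another test is named. The labels do not say whether replicates came from separate mice, so p values measure the spread between libraries alone. Against a group at 0 counts, a fold is a lower bound set by a floor of 3 counts over that group's 3 libraries. With 1 to 3 counts it is a ratio with its 95% counting interval, and such bounds and intervals cover counting error only. The largest changes are named by fitted log2 fold change, whose order near 0 counts depends on the prior count and differs from that of bounds and ratios.

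Il25 itself (ENSMUSG00000040770, chromosome 14, 54932695 to 54935837 in GRCm38), the cytokine gene behind the sort, was read 169, 454 and 359 times in SI-pos 1 to 3 and 0, 1 and 2 times in SI-neg 1 to 3. It was read 220, 324 and 257 times in GB-pos 1 to 3 and 48, 1 and 0 times in GB-neg 1 to 3. The small intestine means were 13.1 ± 6.06 CPM in IL-25+ and 0.0281 ± 0.0258 CPM in IL-25- cells, a ratio of 443 (interval 151 to 2150, adjusted p = 0.000867). The gallbladder means were 8.44 ± 3.11 and 0.234 ± 0.381 CPM, a log2 fold change of 5.04 ± 1.20 (adjusted p = 0.00734). Without GB-neg 1, which held 48 of the 49 counts in its group, that log2 fold change was 8.76 (adjusted p = 0.000278, with a range of 5.02e-06 to 0.0498 over its alternatives). Between tissues the difference in Il25 did not pass the test among IL-25+ cells (-0.63 ± 1.01, adjusted p = 0.7) or among IL-25- cells (ratio 12.4, interval 4.0 to 62.1, adjusted p = 0.121, and a ratio of 0.531 without GB-neg 1). The interaction of tissue and gate was -3.61 ± 1.66 (adjusted p = 0.21).

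**Figure D1:**
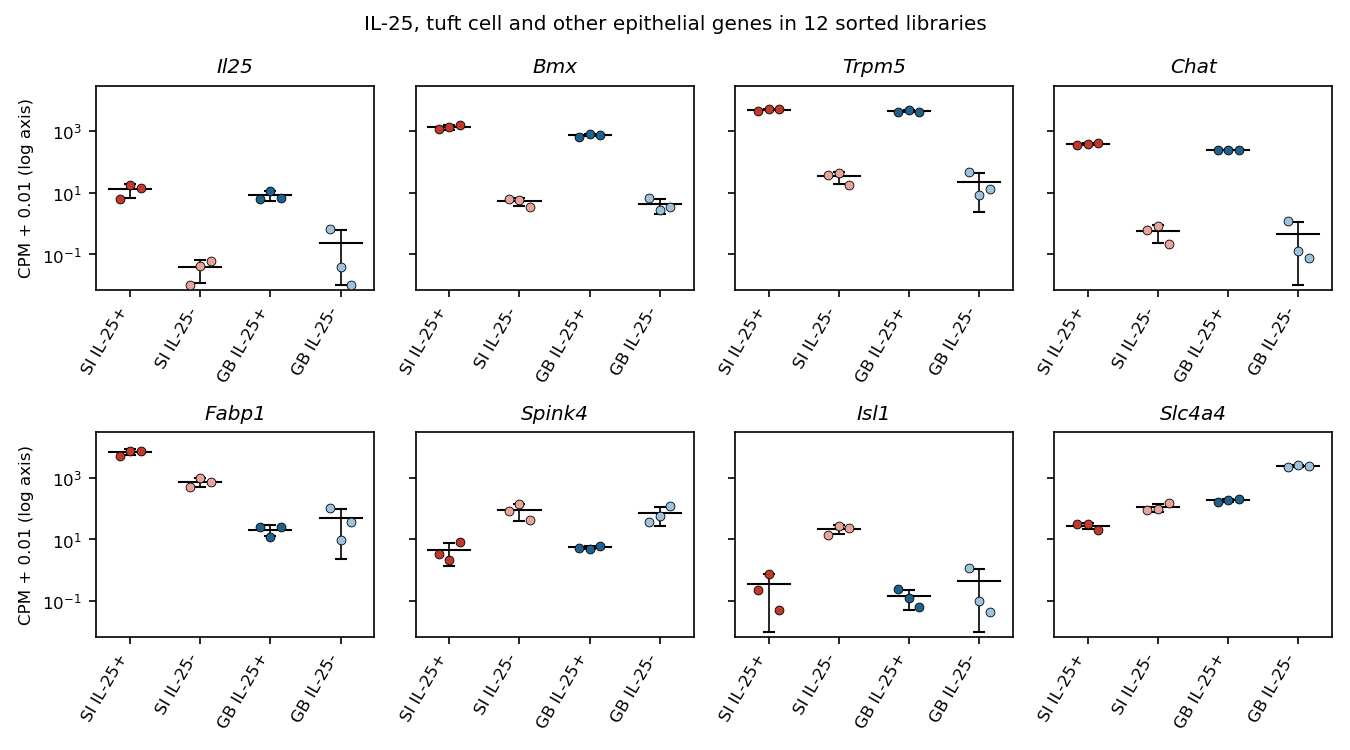
CPM (plus 0.01, log axis) of 8 genes in the 12 libraries, with a point per library and a line and bar for the mean and SD of each group of 3. Bmx, Trpm5 and Chat are higher in IL-25+ cells of both tissues, Spink4 and Slc4a4 are lower, and Fabp1 is higher in IL-25+ cells of the small intestine at 6894 CPM.

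The comparison of IL-25+ with IL-25- small intestine asks which transcripts mark the sorted fraction. All 24 tested tuft identity genes rose in IL-25+ cells, with a median log2 fold change of 7.09. Bmx, a Tec-family kinase (ENSMUSG00000031377, chromosome X, 164192842 to 164258193), went from 5.34 ± 1.55 CPM in IL-25- to 1386 ± 233 CPM in IL-25+ cells, a log2 fold change of 8.02 ± 0.41 (adjusted p = 4.71e-08). Ptpn6, the phosphatase SHP-1, rose by 6.44 ± 0.23 (adjusted p = 3.57e-09). Secretory lineage genes fell: 12 of 13 goblet genes, 11 of 18 enteroendocrine genes and 4 of 8 Paneth genes were lower in IL-25+ cells. Of 16636 genes tested with edgeR quasi-likelihood, 4529 passed, 2405 higher and 2124 lower. The majority direction depended on the fit, with 53.1% higher here, 45.7% under RLE scaling, 43.7% with DESeq2 and 43.7 to 59% over all alternatives.

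Taste transduction genes followed the tuft list, with 7 of 10 higher and 3 not passing. Trpm5, the cation channel of taste and tuft cells (ENSMUSG00000009246, chromosome 7, 143069153 to 143094642), reached 5119 ± 312 CPM in IL-25+ cells and rose by 7.22 ± 0.67 (adjusted p = 1.54e-05). The phospholipase Plcg2 rose by 5.27 ± 0.43 and the IP3 receptor Itpr2 by 3.64 ± 0.35. In the tuft effector and eicosanoid list, which includes Il25 itself, 12 of 14 genes rose. Chat, which encodes the enzyme that makes acetylcholine (ENSMUSG00000021919, chromosome 14, 32408203 to 32465989), rose by 9.46 ± 0.95 to 386 ± 32.2 CPM, and the cyclooxygenase gene Ptgs1 rose by 7.51 ± 0.78. Pla2g4a, a phospholipase that frees arachidonic acid, rose by 3.66 ± 0.28 and Mgst3 by 2.41 ± 0.28, while Mgst2, a related microsomal glutathione transferase, fell by 1.74 ± 0.29 on the log2 scale (adjusted p = 0.000764).

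Among luminal metabolite receptors, 6 of 11 genes rose, 1 fell and 4 did not pass. Ffar3, a receptor for short-chain fatty acids, rose by 6.90 ± 0.45 and the orphan receptor Gprc5c by 6.24 ± 0.40. Chrm3, a muscarinic acetylcholine receptor, fell by 4.85 ± 0.90 on the log2 scale (adjusted p = 0.00149); without SI-pos 1 the change was -7.33 (adjusted p = 0.000583, range 1.88e-08 to 0.0191). Sucnr1, the succinate receptor (ENSMUSG00000027762, chromosome 3, 60081869 to 60087566), had 1132, 1023 and 2173 counts in SI-pos 1 to 3 and 59, 0 and 0 in SI-neg 1 to 3, a log2 fold change of 6.61 ± 1.72 (adjusted p = 0.0167). Without SI-neg 1 it was 13.95 (adjusted p = 0.000942), and with no filter on low counts the adjusted p was 0.0578, within a range of 0.000216 to 0.0578. Gpbar1, a bile acid receptor, had 1 count in the IL-25+ and 6 in the IL-25- small intestine libraries and 0 in the gallbladder, too few to test.

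The tuft-2 immune-type list rose in 9 of 11 genes, among them Tmem176a (5.47 ± 0.29) and Tmem176b (4.39 ± 0.29), which encode membrane proteins found in immune cells. The tuft-1 neuronal-type list split. Atp2a3, a calcium pump, rose by 5.59 ± 0.46 to 8997 ± 905 CPM and the calmodulin-binding Nrgn rose by 7.91 ± 0.64, but Nrep, Dpysl3 and Ddc fell by 2.83 ± 0.61, 3.79 ± 0.82 and 1.48 ± 0.33. Fitted with the small intestine libraries alone, Nrep (adjusted p = 0.0568, range 6.02e-06 to 0.0568) and Dpysl3 (0.0551, range 8.04e-07 to 0.0551) no longer passed, and without SI-pos 3 the Dpysl3 change was -6.31.

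The genes with the largest fitted increases included Colq, the collagen tail of acetylcholinesterase, at least 802-fold higher, and the transcription factor Prdm13, at least 608-fold higher, both with 0 counts in IL-25- libraries. Tslp, a cytokine of type 2 immunity, was higher by a ratio of 1450 (interval 260 to 57400), at 14.1 ± 3.39 CPM. The semaphorin Sema5b rose by 10.5 ± 0.56, the growth-cone protein gene Basp1 by 10 ± 0.83 and the methyltransferase gene Smyd1 by 9.82 ± 1.40. Smyd1 (chromosome 6, 71213940 to 71322233) lies next to Fabp1, described below. The largest fitted decreases included the phospholipase Plb1, at least 274-fold lower (160 without SI-neg 3) and with 0 counts in IL-25+ libraries. Ret, a receptor tyrosine kinase (ENSMUSG00000030110, chromosome 6, 118151745 to 118197718), was lower by a ratio of 2000 (interval 358 to 78900), Stxbp5l by 2080 (374 to 82300), Rgs4 by 1760 (316 to 69600), Sphkap by 1470 (264 to 58100, and 977 without SI-neg 2) and the gut peptide gene Nts by 1380 (473 to 6710). For Nts, SI-neg 2 held 4209 of 5618 counts, and the ratio without it was 489.

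Goblet genes that fell included Spink4, a secreted protease inhibitor (-4.35 ± 0.62), and the glycosyltransferase Galnt12 (-3.57 ± 0.57). Paneth examples were Mptx2 (-7.40 ± 1.70, or -6.23 without SI-neg 2) and Mmp7, which activates defensins (-5.20 ± 1.13), and Isl1, an enteroendocrine transcription factor, fell by 5.99 ± 1.29. Among proliferation genes 10 of 20 fell, including the replication helicase subunit Mcm6 (-3.11 ± 0.44) and Ube2c (-2.66 ± 0.49). Stem cell genes included 5 of 11 lower, with Rnf43 at -2.47 ± 0.48 and Slc12a2 at -1.77 ± 0.36, and Msi1 higher (3.18 ± 0.93, adjusted p = 0.0288). The Msi1 call ended without any of SI-pos 2, SI-pos 3, SI-neg 1, SI-neg 2 or SI-neg 3, with adjusted p from 0.0629 to 0.0826 in those fits and from 3.72e-06 to 0.0894 over all alternatives.

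Of 24 enterocyte genes, 4 fell, among them the brush border enzymes Mgam (-1.97 ± 0.29) and Dpp4 (-1.97 ± 0.30), and Fabp1 rose. Fabp1, a fatty acid binding protein (ENSMUSG00000054422, chromosome 6, 71199827 to 71205023), reached 6894 ± 1530 CPM in IL-25+ against 761 ± 252 CPM in IL-25- cells, a log2 fold change of 3.18 ± 0.71 (adjusted p = 0.00807). The other 19 did not pass, and without SI-neg 3 and GB-neg 1, the libraries that held each other's transcripts, 19 enterocyte genes were lower and 1 higher. Apart from Fabp1, the 22 abundant enterocyte genes lay at 16.6 to 44.7% of their IL-25- mean in each IL-25+ library. Of the gallbladder and cholangiocyte identity list, 8 of 17 fell, such as the keratin Krt19 (-2.63 ± 0.30) and the bicarbonate transporter Slc4a4 (-2.03 ± 0.23). The keratin Krt23 rose by 4.77 ± 0.69, and Prom1 rose by 0.79 ± 0.26 (adjusted p = 0.0385). Without SI-pos 1, 2 or 3, SI-neg 2 or 3, or GB-pos 2 or 3, Prom1 had adjusted p from 0.0515 to 0.128 (0.0132 to 0.128 over all alternatives).

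Bile acid and biliary transport genes divided into 4 lower, such as the water channel Aqp1 (-3.37 ± 0.38) and the chloride channel Cftr (-2.60 ± 0.45), and 2 higher, Slc4a2 (1.70 ± 0.19) and Abcc3 (1.32 ± 0.20). Interferon response genes rose in 7 of 15 cases, including Oasl2 (2.88 ± 0.36) and Oas1a (3.30 ± 0.42). MHC class II genes fell in 4 of 7, with H2-DMb1 at -1.83 ± 0.44. The dissociation stress list, immediate early and heat shock genes that rise when tissue is dispersed, fell in 6 of 16 cases, with Egr1 at -3.86 ± 0.27 and Nr4a1 at -4.41 ± 0.50. In that list Zfp36 rose by 0.79 ± 0.20, but at 0.68 without SI-neg 3 and GB-neg 1 it missed the threshold (adjusted p = 0.0558, range 0.000555 to 0.0558). Among neutrophil chemokine and antimicrobial genes, Tnfaip3, an inhibitor of NF-kB signalling, rose by 2.20 ± 0.26, while Pigr, the polymeric immunoglobulin receptor, fell by 2.15 ± 0.32 and 1 more member fell. Intestinal transcription factors fell in 2 of 10 cases (4 under RLE scaling), including Creb3l3 (-2.21 ± 0.35).

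As whole lists, by camera with a preset correlation, 16 of the 24 lists tested passed in this comparison. The tuft-2 immune-type list passed with an adjusted p of 4.45e-07 and of 0.012 with an estimated correlation. The other 15 did not hold with an estimated correlation: tuft identity (adjusted p = 0.071 there), taste transduction (0.16), tuft effector (0.071), luminal receptors (0.15) and interferon response (0.28) among lists that were higher. Among those that were lower it was 0.13 for gallbladder identity, 0.54 for enterocyte, 0.16 for goblet, 0.32 for Paneth, 0.24 for enteroendocrine, 0.37 for stem, 0.16 for proliferation, 0.11 for hepatocyte, 0.32 for MHC class II and 0.45 for dissociation stress. The median and mean differed in sign for the T cell list (-0.28 and 0.09) and the myeloid list (-0.32 and 0.72), neither of which passed. Adjusted over the list alone, the counts of genes higher and lower changed to 7 and 1 for taste transduction, 2 and 7 for bile acid transport, 2 and 10 for gallbladder identity, 0 and 8 for Paneth and 0 and 15 for enteroendocrine. They changed to 1 and 6 for stem, 0 and 16 for proliferation, 0 and 6 for MHC class II, 8 and 0 for interferon response, 2 and 7 for dissociation stress and 0 and 0 for mitochondrially encoded genes. Without SI-neg 3 and GB-neg 1, 7 Paneth genes were lower. Changing the scaling from TMM to RLE moved the median log2 fold change of all genes by -0.123 here, by 0.119 between the IL-25+ groups and by 0.164 in the interaction.

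The gallbladder comparison asks the same of the IL-25+ fraction of biliary epithelium. All 24 tested tuft identity genes rose there as well, with a median log2 fold change of 8.23. Bmx went from 4.33 ± 2.19 to 758 ± 64.7 CPM (7.44 ± 0.40, adjusted p = 1.08e-07) and Ptpn6 rose by 5.48 ± 0.22 (adjusted p = 2.61e-08). Genes of the surrounding biliary epithelium fell: 10 of 17 gallbladder identity genes and 10 of 19 bile acid and biliary transport genes were lower. Slc4a4 (ENSMUSG00000060961, chromosome 5, 88886818 to 89239653), which moves bicarbonate into epithelial cells, went from 2477 ± 214 to 186 ± 18.3 CPM (-3.73 ± 0.24, adjusted p = 3.38e-07). With edgeR, 4456 genes passed, 2066 higher and 2390 lower, that is 46.4% higher and 44.1 to 50.5% over the alternatives.

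Taste transduction genes rose in 8 of 10 cases, with Trpm5 at 7.63 ± 0.68 (4558 ± 416 CPM in IL-25+ cells), Plcg2 at 5.62 ± 0.44 and Itpr2 at 5.05 ± 0.37. Itpr3, another IP3 receptor, fell by 0.82 ± 0.22 (adjusted p = 0.0151), a call that ended without GB-pos 2 (0.0505) and without both gallbladder libraries numbered 2 (0.112), within a range of 0.00698 to 0.112. Of 14 tuft effector genes 11 rose, including Chat (8.83 ± 0.92), Pla2g4a (2.31 ± 0.26) and Alox5ap (8.46 ± 0.82), which serves leukotriene synthesis. Luminal receptors rose in 5 of 11 cases, including Ffar3 (9.76 ± 0.53) and Gprc5c (3.47 ± 0.35). Sucnr1 had 7, 0 and 26 counts in GB-pos 1 to 3 and 51, 25 and 3 in GB-neg 1 to 3, with a log2 fold change of -0.75 ± 1.5 (adjusted p = 0.756). In the tuft-1 neuronal-type list 4 of 8 rose, with Atp2a3 at 6.01 ± 0.47 and Nrgn at 9.18 ± 0.69, and Ddc fell by 3.26 ± 0.36. In the tuft-2 immune-type list 8 of 11 rose, with the phosphatase Ptprc at 9.02 ± 0.95 and Il13ra1, a subunit of the IL-13 receptor, at 2.7 ± 0.19. Fcer1g was lower in that list (at least 12.1-fold, 0 counts in IL-25+ libraries, adjusted p = 0.0462), with an adjusted p of 0.0526 to 0.18 without any of 10 single libraries (all but SI-pos 2 and GB-neg 1) and a range of 0.0121 to 0.311. For Fcer1g, GB-neg 3 held 45 of the 50 counts, and without it the bound was 1.56-fold and the fitted change -4.21.

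The largest fitted increases were in Tnfrsf8, the receptor CD30 (ENSMUSG00000028602, chromosome 4, 145267137 to 145315164), at least 1390-fold, and the catenin Ctnna3, at least 1110-fold. The growth factor gene Nrg3 was at least 592-fold higher and the myelin glycoprotein gene Mag at least 508-fold higher (300 without GB-pos 3), again with 0 counts in IL-25- libraries. Tlr9, a sensor of unmethylated DNA, was higher by a ratio of 10400 (interval 1870 to 412000), at 75.5 ± 31.9 CPM, and Tcerg1l by a ratio of 5390 (966 to 213000). The largest fitted decreases were in Bag2 (-8.51 ± 2.19), Il22ra1, a subunit of the IL-22 receptor (-8.33 ± 0.68), Tnxb (-7.99 ± 1.98), the purinergic receptor P2ry1 (-7.32 ± 0.79), endothelin-1, Edn1 (-7.02 ± 1.14), and Ptgfr, a prostaglandin receptor (-6.73 ± 1.62). Bag2 missed the threshold without GB-pos 3 (adjusted p = 0.0514, range 0.00017 to 0.0706) and without both gallbladder libraries numbered 2 (0.0706), and Tnxb without the latter pair (0.0632, range 2.85e-05 to 0.0632). Ptgfr missed it without GB-neg 3 (-5.69, adjusted p = 0.051, range 1.06e-05 to 0.051).

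Krt19 fell by 3.46 ± 0.31, Aqp1 by 3.24 ± 0.37 and Cftr by 3.69 ± 0.48 on the log2 scale, while the anion exchanger Slc4a2 rose by 0.96 ± 0.19 (adjusted p = 0.00181). Of 24 enterocyte genes 8 fell, among them Dpp4 (-4.43 ± 0.34) and the glucose transporter Slc2a2 (-3.82 ± 0.30), and without SI-neg 3 and GB-neg 1 the counts were 4 lower and 1 higher. Intestinal transcription factors had 3 of 10 lower, including Creb3l3 (-5.34 ± 0.44) and Hnf4g (-2.74 ± 0.50), and 2 higher, Cdx1 (5.23 ± 0.99) and Hnf4a (0.83 ± 0.25, adjusted p = 0.028). Without GB-neg 1 the Cdx1 change was 8.82 (adjusted p = 1.81e-06, range 6.3e-10 to 0.0149), and Hnf4a missed the threshold without GB-pos 1, GB-pos 2, GB-neg 2 or GB-neg 3 (0.0651 to 0.0947, with a full range of 0.00131 to 0.155). Goblet genes fell in 6 of 13 cases, such as Klk1 (-5.24 ± 0.67) and Spink4 (-3.71 ± 0.60), while Spdef, a goblet lineage transcription factor, rose by 3.88 ± 0.87 (adjusted p = 0.00498). With edgeR 0 of 8 Paneth and 0 of 18 enteroendocrine genes passed, where 1 and 4 had an unadjusted p under 0.05, DESeq2 called 2 and 3, and limma-voom called 1 and 2. Enteroendocrine genes such as Chgb (2.54 and 2.6 CPM in GB-neg 2 and 3) and Gcg (0.266 and 0.13) had little to lose there.

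Stem cell genes went both ways. Lgr5, a receptor for R-spondins (ENSMUSG00000020140, chromosome 10, 115450311 to 115587780), reached 119 ± 12.8 CPM in IL-25+ and 0.699 ± 1.13 CPM in IL-25- cells (7.27 ± 1.22, adjusted p = 0.00155), Ascl2 rose by 5.25 ± 1.01 and Msi1 by 4.68 ± 1.03. Without GB-neg 1 the Lgr5 and Msi1 changes were 11.2 and 8.29. Slc12a2 (-1.33 ± 0.36), Cdca7 (-3.94 ± 1.04) and Tnfrsf19 (ratio 95 lower, interval 16.7 to 3780) fell. Slc12a2 missed the threshold without GB-pos 1 (adjusted p = 0.0605) or GB-neg 2 (0.0625, range 0.00447 to 0.0792), and Cdca7 without GB-pos 2 (0.0503) or GB-neg 1 (-2.28, 0.0723, range 0.000164 to 0.143). For Tnfrsf19, GB-neg 1 held 122 of 131 counts, and without it the ratio was 13.7 and the fitted change -3.33. Tnfrsf19 missed the threshold without any of 9 single libraries (all but SI-pos 2, GB-neg 2 and GB-neg 3), at 0.0518 to 0.215 there and 0.00699 to 0.244 over all alternatives. Proliferation genes fell in 4 of 20 cases, with Mcm2 at -2.11 ± 0.45 and Mcm6 at -1.67 ± 0.42, and the centromere gene Cenpa rose by 3.04 ± 0.87 (adjusted p = 0.0206). The Cenpa change was 4.60 without GB-neg 1 and missed the threshold without GB-neg 2 (0.0675, range 0.000286 to 0.127).

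MHC class II genes fell in 6 of 7 cases, with H2-DMb1 at -4.30 ± 0.57, which missed the threshold with the gallbladder libraries fitted alone (adjusted p = 0.0645, range 2.23e-07 to 0.0645); without SI-neg 3 and GB-neg 1, 3 of the 7 were lower. The dissociation stress list fell in 12 of 16 cases, with Zfp36 going from 7412 ± 180 to 1323 ± 52.3 CPM (-2.49 ± 0.21) and Fos at -3.28 ± 0.32. Interferon response genes had 1 higher, Rsad2 (4.35 ± 0.81), and 3 lower of 15, including the antiviral GTPase gene Mx1 (-5.99 ± 0.58). Neutrophil chemokine and antimicrobial genes fell in 6 of 15 cases, with Tnfaip3 at -2.92 ± 0.27 and the chemokine Cxcl16 at -4.71 ± 0.52. Cd79b, a signalling chain of the B cell receptor, rose by 4.51 ± 0.68, Csf1r, the receptor of macrophage growth factor, was lower by a ratio of 528 (interval 146 to 4360, and 215 without GB-neg 1), and mt-Co1 fell by 2.12 ± 0.38 with 2 more mitochondrial genes (6 of 8 lower without SI-neg 3 and GB-neg 1). In the hepatocyte list, Ttr fell by 2.92 ± 0.59 and Trf rose by 6.10 ± 1.41. Without the gallbladder libraries numbered 2 the Trf change was 6.31 and missed the threshold (adjusted p = 0.0528, range 3.56e-06 to 0.0528).

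By camera 14 of 24 lists passed. Tuft identity (adjusted p = 1.47e-26), tuft-2 immune-type (4.4e-06) and gallbladder identity (0.000172) also passed with an estimated correlation, at 0.04, 0.021 and 0.04. With an estimated correlation the adjusted p was 0.11 for taste transduction, 0.059 for tuft effector, 0.26 for luminal receptors, 0.28 for tuft-1, 0.059 for bile acid transport, 0.62 for enterocyte and 0.63 for goblet. It was 0.48 for proliferation, 0.39 for MHC class II, 0.32 for neutrophil chemokine and antimicrobial and 0.13 for dissociation stress. The luminal receptor list had a median of -0.54 (0.0 with genes at 0 counts set to their bounds), a mean of 1.55 and a test direction of higher. The stem list had a median of -0.62 and a mean of -0.13 against a test direction of higher, and the interferon list a median of 0.59 and a mean of -0.44, and neither passed. Adjusted over the list alone, counts higher and lower became 5 and 2 for luminal receptors, 1 and 11 for bile acid transport, 1 and 12 for gallbladder identity, 0 and 19 for enterocyte, 2 and 5 for intestinal transcription factors and 3 and 4 for stem. Without SI-neg 3 and GB-neg 1, the stem list had 4 higher and 1 lower and the enteroendocrine list 3 higher, and without the gallbladder libraries numbered 2 the interferon list had 3 higher and 1 lower. Over the list alone the counts became 1 and 6 for proliferation, 1 and 1 for B and plasma cell, 1 and 4 for myeloid, 0 and 7 for neutrophil chemokine and antimicrobial, 0 and 14 for dissociation stress and 0 and 5 for mitochondrially encoded genes.

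**Figure D2:**
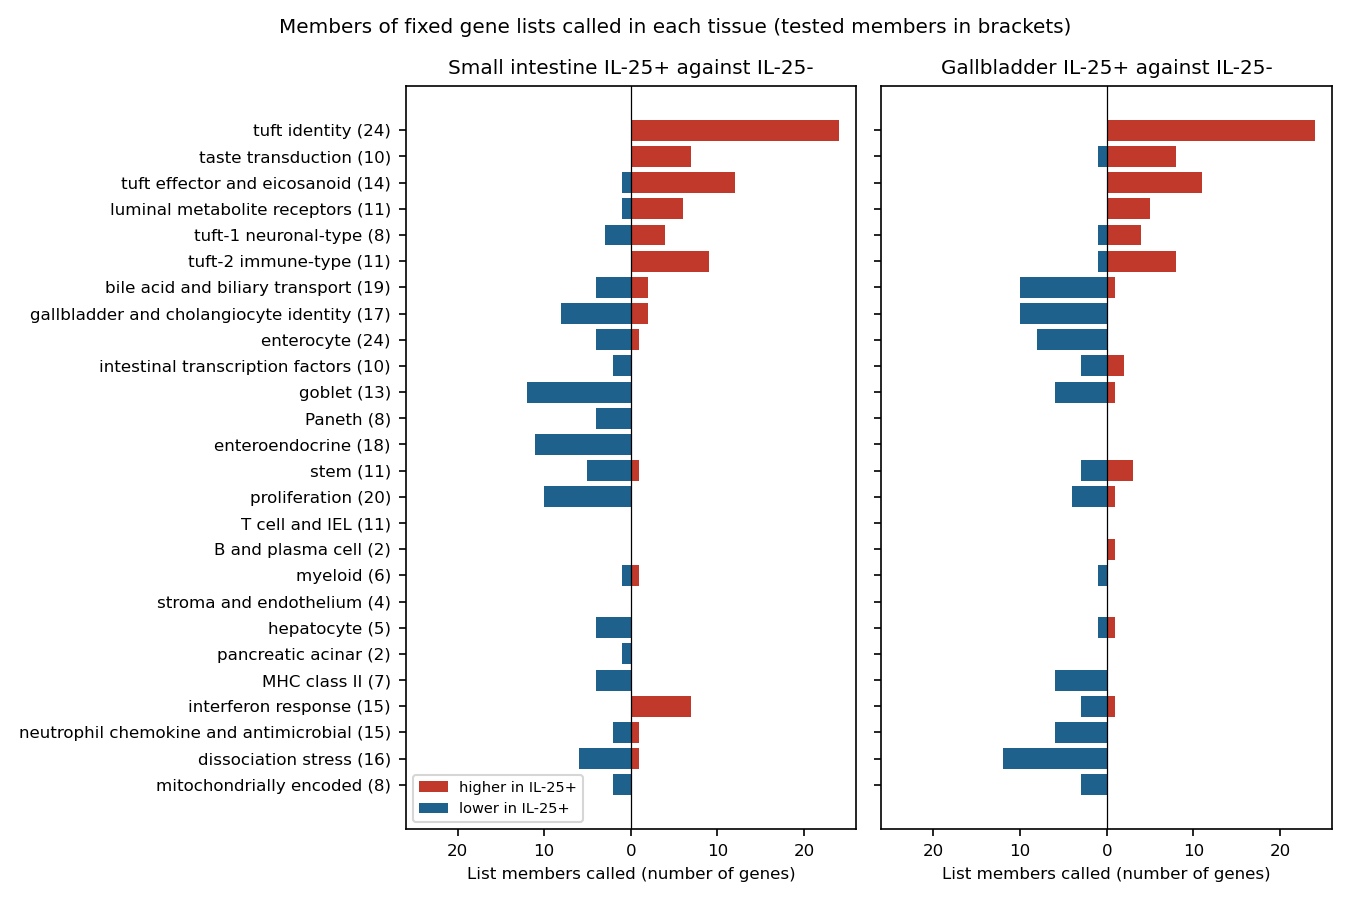
Number of list members called higher (right) or lower (left) in IL-25+ cells of the small intestine and the gallbladder, for 26 lists with the number of tested members in brackets. All 24 tested tuft identity genes are higher in both panels, and 12 goblet genes are lower in the small intestine against 6 in the gallbladder.

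The gate changed many of the same genes in both tissues. Of 16636 genes, 1176 were higher and 976 lower in IL-25+ cells of both, 2152 in all, where independent calls would share 298.7 and 305.1, and 191 changed in opposite directions. Tuft genes such as Bmx and Trpm5 were in the first set, and Krt19, Spink4 and Aqp1 in the second. Lower in the small intestine and higher in the gallbladder was, for example, Nrep, described in the next comparisons. Across genes the log2 fold changes of both tissues had a Pearson r of 0.49 and a Spearman rho of 0.50 (0.36 and 0.39 without SI-neg 3 and GB-neg 1, with 1603 shared genes), as a description in which genes are not independent replicates.

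**Figure D3:**
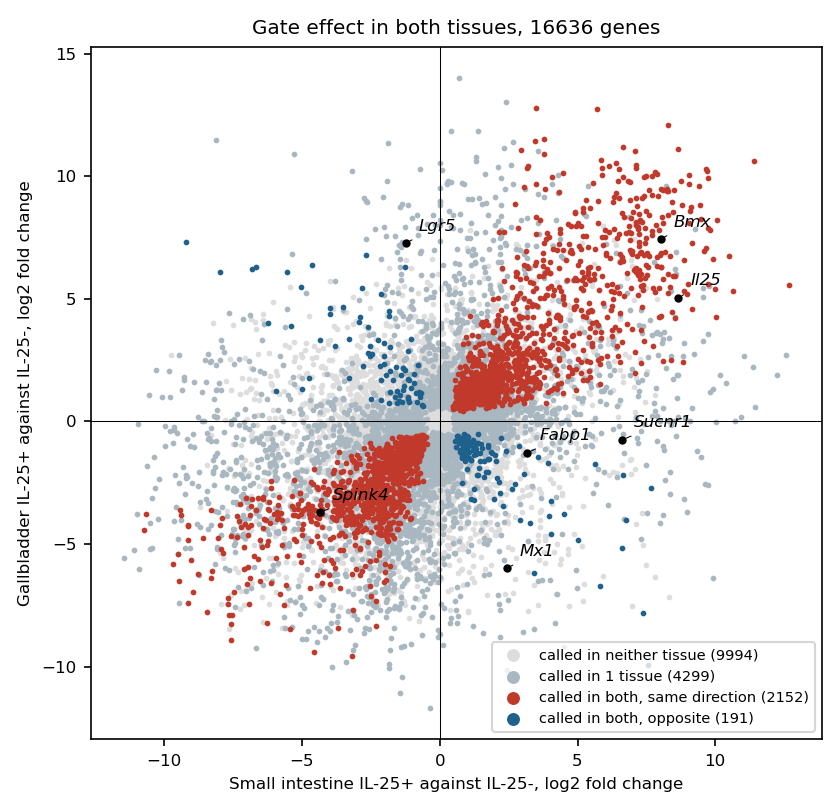
Log2 fold change of IL-25+ against IL-25- cells in the small intestine (x axis) and the gallbladder (y axis), with a point per gene for 16636 genes coloured by the tissues in which the gene was called. Most genes called in both tissues lie in the quadrants of equal sign (2152 against 191 of opposite sign), and Mx1 and Fabp1 lie outside them.

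The comparison of IL-25+ cells between gallbladder and small intestine asks how the sorted fractions differ between the organs. Gallbladder identity genes were higher in gallbladder IL-25+ cells in 10 of 17 cases, and all 24 enterocyte genes, 8 of 10 intestinal transcription factors and all 7 MHC class II genes were lower. Slc4a4 was higher by 2.75 ± 0.23 (adjusted p = 6.08e-06) and Hhex, a transcription factor of the biliary lineage, by 3.49 ± 0.41. H2-Aa, a chain of the antigen-presenting class II molecule (ENSMUSG00000036594, chromosome 17, 34282744 to 34287823), stood at 0.0558 ± 0.0481 CPM against 15.5 ± 1.94 CPM (-8.12 ± 0.79, adjusted p = 1.65e-05), where small intestine IL-25- cells had 59.3 ± 12.7 CPM. The class II genes with at least 50 CPM in IL-25- cells, 3 in all, had a median of 29, 26.7 and 22.6% of that level in SI-pos 1 to 3, near the share of the enterocyte genes. Fabp1 stood at 20.8 ± 7.76 against 6894 ± 1530 CPM (-8.37 ± 0.91). With edgeR, 3938 genes passed, 1753 higher and 2185 lower. The majority direction again depended on the fit, with 44.5% higher here, 51.5% under RLE scaling, 51.9% with DESeq2 and 42 to 52.6% over all alternatives.

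Within the tuft lists, 7 of 24 identity genes were lower in the gallbladder and 17 did not pass, and without SI-neg 3 and GB-neg 1 the counts were 13 lower and 2 higher. Matk, a kinase related to Csk (ENSMUSG00000004933, chromosome 10, 81252935 to 81263365), stood at 38.6 ± 18.6 against 1424 ± 260 CPM (-5.21 ± 0.45, adjusted p = 8.77e-06). Il17rb, a subunit of the IL-25 receptor, was lower (-2.95 ± 0.54), as were the sialic acid lectin gene Siglecf (-2.18 ± 0.46) and Ptpn6 (-1.02 ± 0.18). Taste genes had 3 of 10 higher, including Tas1r3, a subunit of the sweet and umami receptors (3.03 ± 0.50), and Itpr2 (1.28 ± 0.32), and Itpr3 lower (-0.95 ± 0.22). In the effector list 4 of 14 were lower, including Mgst2 (-2.52 ± 0.30) and Mgst3 (-2.01 ± 0.27). Slc18a3, the vesicular acetylcholine transporter, was at least 365-fold lower (117-fold without SI-pos 3, which held 662 of 846 counts), with 0 counts in the gallbladder IL-25+ libraries, and its annotated gene (chromosome 14, 32462438 to 32464850) lies within that of Chat.

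Sucnr1 was lower in gallbladder IL-25+ cells, at 0.301 ± 0.360 against 57.3 ± 26.7 CPM (-7.50 ± 1.80, adjusted p = 0.0128). It was 1 of 6 luminal receptors of 11 that were lower, with the short-chain fatty acid receptors Ffar3 (-2.44 ± 0.37) and Ffar2 (a ratio of 533, interval 95.2 to 21100), while Chrm3 was higher (6.46 ± 0.94). In the tuft-1 neuronal-type list Nrep (ENSMUSG00000042834, chromosome 18, 33437019 to 33464029) stood at 232 ± 13.5 against 0.544 ± 0.567 CPM (8.73 ± 0.73, adjusted p = 8.32e-06) and Dpysl3, a cytoskeletal protein of growing axons, was higher by 8.64 ± 0.93. Ddc (-3.64 ± 0.37) and Atp2a3 (-1.84 ± 0.39) were lower, and 1 more of the 8 was higher. In the tuft-2 immune-type list Il13ra1 was higher (1.83 ± 0.18) and 3 of 11 were lower, including Tmem176b (-1.17 ± 0.26) and Tmem176a (-1.10 ± 0.24).

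The largest fitted differences in favour of the gallbladder were in Sema3a, an axon guidance cue, at least 278-fold, and the potassium channel Kcnq3, at least 224-fold, both with 0 counts in the small intestine IL-25+ libraries. For Kcnq3, GB-pos 2 held 782 of 871 counts, and without it the bound was 31.5-fold. Fjx1 was higher by a ratio of 1450 (interval 259 to 57200), N-cadherin, Cdh2, by 1140 (204 to 44900), Sox7 by 1080 (194 to 42800) and the metalloprotease Adamts7 by 995 (275 to 8220). In favour of the small intestine, Cst6, a cysteine protease inhibitor (ENSMUSG00000024846, chromosome 19, 5344705 to 5349574), differed by a ratio of 7320 (1310 to 289000), at 75 ± 25.1 CPM there. Nat8 was at least 428-fold lower in the gallbladder, Etos1 lower by a ratio of 1620 (448 to 13400), the class I gene H2-Q7 by -10.59 ± 1.29 and the iron oxidase gene Heph by -10.49 ± 1.43. H2-Q7 has close paralogs, between which 50 bp reads can be shared.

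Bile acid and biliary transport genes went both ways, with 8 of 19 lower and 4 higher. The sterol exporters Abcg8 (-8.51 ± 0.76) and Abcg5 (-6.45 ± 0.63) were lower. Aqp1 (3.20 ± 0.37), the bile acid importer Slc10a2 (5.59 ± 1.20, or 4.27 without GB-pos 2) and the nuclear receptor Nr0b2 (a ratio of 43.5, interval 14.6 to 213, and 16.9 without GB-pos 3) were higher. Mgam (-4.17 ± 0.32) and Dpp4 (-4.24 ± 0.33) were among the enterocyte genes, and Creb3l3 (-6.32 ± 0.45) and Hnf4g (-4.13 ± 0.54) among the transcription factors. The goblet list had 3 of 13 lower, with Klk1 at -5.25 ± 0.67, and Spdef higher (4.91 ± 0.93). In the Paneth list Mmp7 was higher (4.36 ± 1.10, adjusted p = 0.0165), and 7 of 8 did not pass. Without SI-pos 1 the Mmp7 difference was 4.44 and missed the threshold (adjusted p = 0.058, range 0.00074 to 0.058). Stem genes had 5 of 11 lower, with Slc12a2 at -1.85 ± 0.36, and 2 higher, with Ascl2 at 3.96 ± 0.95, and proliferation genes had 6 of 20 lower, including Ube2c (-4.44 ± 0.55) and Top2a (-2.45 ± 0.49). With edgeR 0 of 18 enteroendocrine genes passed, 3 had an unadjusted p under 0.05, DESeq2 called 3 and limma-voom 1.

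Interferon response genes were lower in 9 of 15 cases, including Mx1 (ENSMUSG00000000386, chromosome 16, 97447035 to 97462907) at 0.240 ± 0.146 against 108 ± 38.0 CPM (-8.75 ± 0.64, adjusted p = 2.6e-06) and Ifit1 (-3.85 ± 0.55). H2-DMb1 was at -7.10 ± 0.61. Dissociation stress genes were higher in 8 of 16 cases, with Egr1 at 4.82 ± 0.29 and Nr4a1 at 4.86 ± 0.51. Neutrophil chemokine and antimicrobial genes had 5 of 15 lower, with Tnfaip3 at -2.60 ± 0.27, and 2 higher, including Wfdc2, a secreted protease inhibitor, at a log2 fold change of 6.32. Both tested B and plasma cell genes were higher (1 of 2 without the gallbladder libraries numbered 2), with Cd79b at 7.17 ± 0.79, and Cd14, a lipopolysaccharide co-receptor, was higher by 3.81 ± 0.87 in a myeloid list with 1 member lower. Ttr, a plasma carrier of thyroid hormone, was higher by 6.62 ± 0.75 and Trf, the transferrin gene, at least 74.7-fold. Of the exon bases of Trf, 63.5% are shared with another annotated gene on the same strand. Mitochondrial genes were lower in 3 of 8 cases, with mt-Co1 at -2.10 ± 0.38 and mt-Cytb at -1.62 ± 0.34.

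By camera 9 of 24 lists passed, and gallbladder identity (adjusted p = 2.68e-07) also passed with an estimated correlation, at 0.016. With an estimated correlation the adjusted p was 0.23 for the enterocyte, intestinal transcription factor, MHC class II and interferon lists, 0.42 for proliferation, 0.56 for T cell, 0.32 for dissociation stress and 0.59 for mitochondrially encoded genes. T cell genes were lower in 6 of 11 cases, but in 1 of 11 without the gallbladder libraries numbered 2, which also left 3 stem genes lower. Without SI-neg 3 and GB-neg 1, 5 tuft-2, 5 goblet, 5 Paneth and 2 enteroendocrine genes were lower, again only through the shared scaling and dispersion. Median, mean and test differed in sign for taste transduction (-0.23, 0.34, higher), stroma (-0.27, 0.29, lower) and neutrophil chemokine and antimicrobial genes (-0.41, 0.09, lower), and none of these 3 passed. Adjusted over the list alone, counts higher and lower became 0 and 8 for tuft identity, 4 and 1 for taste transduction, 2 and 6 for luminal receptors, 1 and 7 for tuft-2, 5 and 9 for bile acid transport, 13 and 0 for gallbladder identity and 0 and 9 for intestinal transcription factors. They became 1 and 4 for goblet, 1 and 5 for Paneth, 0 and 8 for proliferation, 0 and 8 for T cell, 2 and 1 for myeloid, 0 and 12 for interferon, 10 and 0 for dissociation stress and 0 and 4 for mitochondrially encoded genes.

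The comparison of IL-25- cells between tissues sets the bulk of gallbladder epithelium against that of the small intestine. Gallbladder identity genes were higher in the gallbladder in 13 of 17 cases, among them Slc4a4 (4.45 ± 0.25, adjusted p = 5.07e-07). Lower were 23 of 24 enterocyte genes, 11 of 13 goblet genes, 10 of 18 enteroendocrine genes and all 7 MHC class II genes. Muc2, the main mucin of goblet cells (ENSMUSG00000025515, chromosome 7, 141690340 to 141754693), stood at 34.2 ± 53.4 against 7406 ± 7320 CPM (-7.75 ± 1.75, adjusted p = 0.0114, and -6.57 without SI-neg 2), though it missed the threshold with the IL-25- libraries fitted alone (0.0569, range 2.14e-09 to 0.0569). With edgeR, 4099 genes passed, 2160 higher and 1939 lower, that is 52.7% higher and 49.1 to 57.8% over the alternatives.

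The largest fitted differences in favour of the gallbladder were in the chemokine scavenger Ackr3 (ENSMUSG00000044337, chromosome 1, 90203980 to 90216751), higher by a ratio of 1010 (interval 182 to 40100), Pmfbp1 (584, interval 161 to 4830), Evc2 (408, interval 139 to 1980) and Stk32b (404, interval 138 to 1960, and 180 without GB-neg 3). Gabrp, a GABA receptor subunit, was higher by 8.56 ± 1.59 (7.05 without GB-neg 2) and the vessel growth factor gene Angpt1 by 8.46 ± 1.46. In favour of the small intestine were Ido1, which degrades tryptophan (-10.14 ± 2.17), the goblet genes Zg16 (-9.94 ± 2.39) and Clca1 (-8.49 ± 2.01), Fer1l6 (-8.01 ± 1.64) and the pancreatic colipase gene Clps (-7.96 ± 1.86). Without SI-neg 2 these 5 were at -7.08, -6.93, -6.76, -6.72 and -5.88. Under limma-voom, Ido1 (adjusted p = 0.0721, range 3.39e-07 to 0.0721) and Zg16 (0.0851, range 1.17e-08 to 0.0851) missed the threshold, Zg16 also without GB-neg 2 (0.0512) or GB-neg 3 (0.0531). Without GB-neg 1 the Fer1l6 change was -12.82, and without both SI-neg 3 and GB-neg 1 the Clps change was -12.26.

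Among enterocyte genes Mgam (-2.40 ± 0.29) and Dgat1, which makes triglycerides (-4.0 ± 0.62), were lower, and Slc2a2 was higher (0.78 ± 0.26, adjusted p = 0.0478). The Slc2a2 call ended without any of SI-pos 1, SI-pos 2, SI-neg 1, SI-neg 2, SI-neg 3 or GB-neg 3 (adjusted p from 0.0531 to 0.207, with a range of 0.0144 to 0.207 over all alternatives). Intestinal transcription factors were lower in 8 of 10 cases, with Hnf4a at -2.48 ± 0.27 and Creb3l3 at -3.20 ± 0.37, and Gata5 was higher (0.96 ± 0.21). Klk1 (-3.51 ± 0.57), the disulfide isomerase Agr2 (-6.06 ± 1.02) and Isl1 (-5.59 ± 1.25) were among the secretory genes, and 6 of 8 Paneth genes were lower, 2 of 8 without the gallbladder libraries numbered 2. Stem genes were lower in 7 of 11 cases, with Slc12a2 at -2.29 ± 0.37 and the Wnt target Axin2 at -5.87 ± 1.10. Proliferation genes were lower in 13 of 20 cases (8 of 20 without SI-neg 3 and GB-neg 1), with Ube2c at -4.32 ± 0.53 and Top2a at -3.67 ± 0.51. Bile acid and biliary transport genes had 7 of 19 higher, with Aqp1 at 3.07 ± 0.37, and 7 lower, with Abcg5 at -4.78 ± 0.56 and Abcc2 at -5.93 ± 1.07.

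Tuft identity genes were lower in 10 of 24 cases and in 20 of 24 without SI-neg 3 and GB-neg 1. Matk was at -4.04 ± 0.47 and Kctd12 at -3.06 ± 0.37, with 62.8% of the exon bases of Kctd12 covered by a gene on the other strand, which these reads cannot separate. The taste G protein gene Gnat3 was higher (4.62 ± 0.75) and 1 of 10 taste genes was lower. In the effector list Mgst2 (-4.05 ± 0.32) and Mgst3 (-1.53 ± 0.27) were lower and Pla2g4a higher (1.19 ± 0.25). Luminal receptors had 3 of 11 higher, with Gprc5c at 2.10 ± 0.33 and Chrm3 at 3.63 ± 0.76, and 2 lower, Ffar3 (-5.30 ± 0.46) and Ffar2 (-6.45 ± 1.09). Tuft-1 genes had 3 of 8 higher, with Dpysl3 at 3.95 ± 0.72, and 2 lower, Atp2a3 (-2.26 ± 0.39) and Ddc (-1.86 ± 0.34). Tuft-2 genes had 4 of 11 higher, with Tmem176a at 2.54 ± 0.25 and S100a11 at 3.10 ± 0.38, and Ptprc lower (-3.11 ± 0.75, or -1.78 without SI-neg 2, adjusted p = 0.0208). Ptprc missed the threshold under limma-voom (0.103, range 5.83e-06 to 0.103). Sucnr1 was at -0.14 ± 1.45 (adjusted p = 0.963), and at 7.20 without SI-neg 1, which held all 59 counts of its group (adjusted p = 0.043, range 0.043 to 1.0).

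Dissociation stress genes were higher in the gallbladder in 12 of 16 cases, with Zfp36 (ENSMUSG00000044786, chromosome 7, 28376784 to 28380253) at 7412 ± 180 against 746 ± 133 CPM (3.31 ± 0.21, adjusted p = 1.03e-06) and Egr1 at 3.49 ± 0.27. Neutrophil chemokine and antimicrobial genes had 4 of 15 higher, with Tnfaip3 at 2.51 ± 0.26 and Cxcl16 at 3.04 ± 0.48, and 2 lower, including the lectin Reg3b (-5.38 ± 1.32), a gene with a close paralog, Reg3g. H2-DMb1 (-4.63 ± 0.50) and H2-Aa (-5.43 ± 0.63) were among the class II genes, and Zbp1, a sensor of nucleic acids (-5.05 ± 0.88), was 1 of 2 interferon response genes of 15 that were lower. Pou2af1, a B cell coactivator, was higher (5.66 ± 1.18), as were Ttr (4.46 ± 0.64) and the pancreatic chymotrypsinogen gene Ctrb1 (7.37 ± 1.44).

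By camera 13 of 24 lists passed, and gallbladder identity (adjusted p = 1.74e-09) also passed with an estimated correlation, at 0.007. With an estimated correlation the adjusted p was 0.36 for tuft identity and Paneth, 0.47 for T cell, 0.53 for mitochondrially encoded genes, and 0.19 for the enterocyte, intestinal transcription factor, goblet, enteroendocrine, stem, proliferation, MHC class II and dissociation stress lists. Without SI-neg 3 and GB-neg 1, 6 effector and 16 enteroendocrine genes were lower, and without the gallbladder libraries numbered 2, 6 tuft identity, 3 tuft-2, 6 enteroendocrine, 7 proliferation and 0 of 11 T cell genes were. Median, mean and test differed in sign for taste transduction (-0.54, 0.15, lower), effector (0.04, -0.04, lower), luminal receptors (0.0, -0.09, higher) and tuft-2 genes (-1.13, -0.67, higher), and none of these 4 passed. Adjusted over the list alone, counts higher and lower became 3 and 3 for tuft-1, 4 and 3 for tuft-2, 8 and 7 for bile acid transport, 14 and 0 for gallbladder identity, 0 and 7 for Paneth and 0 and 17 for enteroendocrine. They became 0 and 10 for stem, 0 and 16 for proliferation, 0 and 7 for T cell, 7 and 3 for neutrophil chemokine and antimicrobial and 0 and 3 for mitochondrially encoded genes. The tissue difference had the same direction in IL-25+ and IL-25- cells for 1796 genes, 837 higher and 959 lower in the gallbladder (227.6 and 254.7 if calls were independent), and opposite directions for 180, with a Pearson r of 0.52 and a Spearman rho of 0.46 across genes.

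**Figure D4:**
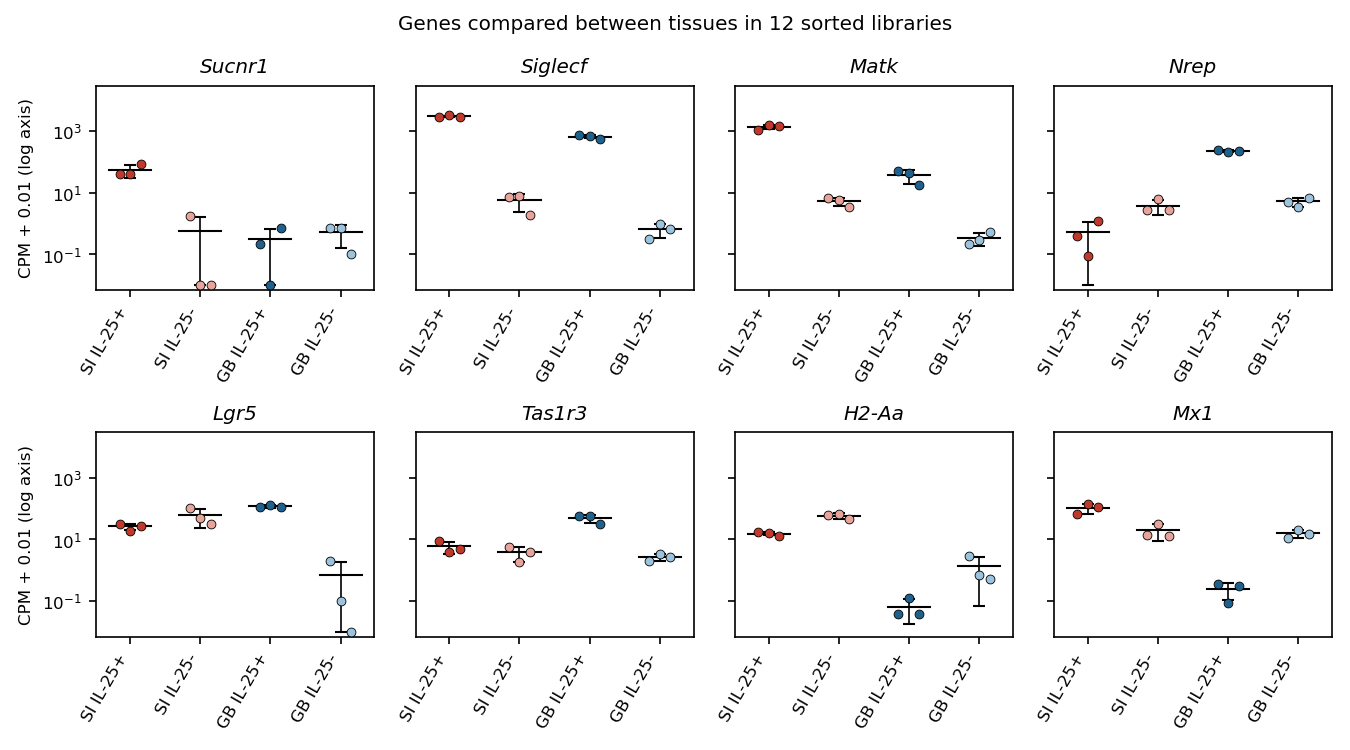
CPM (plus 0.01, log axis) of 8 genes in the 12 libraries, with a point per library and a line and bar for the mean and SD of each group of 3. Sucnr1, Siglecf, Matk, H2-Aa and Mx1 are lower in gallbladder than in small intestine IL-25+ cells, and Nrep, Tas1r3 and Lgr5 are highest in gallbladder IL-25+ cells, Lgr5 at a mean of 119 CPM.

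The interaction of tissue and gate tests whether the effect of the gate differs between tissues, as the gallbladder log2 fold change minus that of the small intestine. Nrep (8.28 ± 0.85, adjusted p = 0.000125), Tas1r3 (3.54 ± 0.67) and Lgr5 (8.50 ± 1.5) had a positive interaction, and Mx1 (-8.43 ± 0.74, adjusted p = 3.71e-05), Tmem176a (-3.64 ± 0.35) and Gprc5c (-2.77 ± 0.46) a negative one. With edgeR, 1536 genes passed, 604 positive and 932 negative, so that 39.3% were positive under TMM scaling and 51.2% of 1522 under RLE scaling (34.3 to 51.6% over all alternatives). For Sucnr1 the interaction was -7.36 ± 2.20 (adjusted p = 0.064), and it passed without SI-neg 1 (-14.7, adjusted p = 0.00365, range 0.00365 to 0.167), under limma-voom (0.00911) and with a stricter filter (0.0497).

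The largest fitted positive interactions were in Gsg1l (16.54 ± 3.79), Apba1 (14.07 ± 2.34, or 12.58 without SI-neg 2), Fxyd6, a regulator of the sodium pump (13.0 ± 1.30), Adamts7 (11.85 ± 1.40), Nrg3 (11.4 ± 2.47) and Cd72, a B cell co-receptor (11.2 ± 1.72). Fitted values this large rest on groups at or near 0 counts. In the small intestine, Fxyd6 stood at 0.107 ± 0.118 CPM in IL-25+ and 11.2 ± 3.04 in IL-25- cells, and in the gallbladder at 32.1 ± 11.9 and 0.387 ± 0.320. Cd72 stood at 57.2 ± 13.3 CPM in gallbladder IL-25+ cells and under 1 CPM on average in the other 3 groups; 41.6% of its exon bases are covered by a gene on the other strand. Gsg1l lost its call without SI-pos 1, 2 or 3 or GB-neg 2 (adjusted p = 0.0538 to 0.0779). Without SI-neg 1, with all SI-neg counts (1021 and 7), Gsg1l stood at 5.14 ± 46.58 (0.981) and Nrg3 had no usable fit (SE 13807).

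The largest fitted negative interactions were in Slc18a3 (-12.33 ± 2.67), Anxa10 (-11.8 ± 1.75), Apol9b (-8.99 ± 2.04, or -6.32 without GB-neg 2), Ppfia2 (-8.75 ± 2.54), Mx2 (-8.63 ± 1.37, or -7.28 without the gallbladder libraries numbered 2) and Mx1. Anxa10, an annexin (ENSMUSG00000031635, chromosome 8, 62057042 to 62123150), stood at 5.79 ± 3.77 CPM in IL-25+ and 0.0522 ± 0.0664 in IL-25- small intestine cells, and at 0.384 ± 0.510 and 14.2 ± 6.64 in the gallbladder. Slc18a3 lost its call without SI-pos 3 (-10.62, adjusted p = 0.0505) or GB-neg 1 (all 3 gallbladder counts, SE 14545). Apol9b lost it without GB-pos 1 (0.0557) or GB-pos 3 (0.0533, range 1.25e-05 to 0.089). Ppfia2 lost it without any of 10 single libraries (all but GB-neg 2 and GB-neg 3), at 0.0558 to 0.93 there and -2.19 without GB-neg 1 (range 0.00515 to 0.958).

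By list, tuft identity had 3 of 24 genes positive and 2 negative (14 and 0 without SI-neg 3 and GB-neg 1), taste 1 positive, Tas1r3, and 1 negative, Gnat3 (-4.92 ± 0.95), of 10, and luminal receptors 1 positive and 3 negative of 11, with Gabbr1, a GABA receptor, at -1.62 ± 0.32. Tuft-1 had 2 positive and 1 negative of 8, tuft-2 1 positive and 3 negative of 11, with Tmem176b at -2.82 ± 0.36, and the effector list 1 positive and 2 negative of 14. Bile acid transport genes were negative in 4 of 19 cases, with Abcc3 at -1.32 ± 0.28, and gallbladder identity genes in 5 of 17, with Slc4a4 at -1.70 ± 0.31. Enterocyte genes were negative in 4 of 24 cases, with Slc2a2 at -2.22 ± 0.38 and Dpp4 at -2.46 ± 0.42, and intestinal transcription factors had 1 positive and 1 negative of 10. Spdef (9.28 ± 1.28) was the 1 goblet gene of 13, and Lgr5 and Ascl2 (6.75 ± 1.31, or 5.36 without SI-neg 1) were among 3 positive stem genes of 11. Interferon genes were negative in 5 of 15 cases, with Oasl2 at -2.29 ± 0.48 and Oas1a at -2.49 ± 0.55. In dissociation stress 4 of 16 were negative, with Zfp36 at -3.28 ± 0.28 and Junb at -2.49 ± 0.43, and 1 positive. Tnfaip3 (-5.11 ± 0.38), Cd79b (6.0 ± 0.94, or 4.83 without SI-neg 3) and Trf (11.67 ± 2.18, SI counts 0 to 7) each were the 1 call in their lists. MHC class II and myeloid genes each had 1 negative.

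By camera 8 of 24 lists passed, and none of the 8 did with an estimated correlation. Negative were bile acid transport (adjusted p = 0.0127, and 0.49 with an estimated correlation) and interferon response (0.00126 and 0.55). Positive were goblet (0.00126 and 0.56), Paneth (0.0251 and 0.56), enteroendocrine (5.86e-09 and 0.49), stem (0.000576 and 0.55), proliferation (0.0276 and 0.56) and hepatocyte genes (0.000576 and 0.31). The Paneth, enteroendocrine and proliferation lists passed with 0 of 8, 18 and 20 members called by edgeR, where 0, 5 and 2 had an unadjusted p under 0.05, and DESeq2 and limma-voom each called 0, 4 and 1. Without SI-neg 3 and GB-neg 1, positive genes numbered 11 for enteroendocrine, 3 each for taste, effector, goblet and intestinal transcription factors, 4 for enterocyte and 5 for stem, and negative ones 2 for bile acid transport and 0 for effector. Without the gallbladder libraries numbered 2, tuft identity had 1 positive and 0 negative, and negative genes numbered 2 for bile acid transport and 3 for interferon. Under RLE scaling 0 tuft identity genes were negative. Adjusted over the list alone, counts positive and negative became 4 and 3 for tuft identity, 2 and 1 for taste, 1 and 3 for effector, 2 and 4 for luminal receptors, 3 and 2 for tuft-1 and 1 and 5 for gallbladder identity. They became 2 and 3 for intestinal transcription factors, 4 and 0 for stem, 0 and 2 for MHC class II, 0 and 6 for interferon and 3 and 6 for dissociation stress.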

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

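The tests of transferred and carried-over transcripts were chosen after the values had been seen, and the splits of the samples were planned.

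Of the 164 genes with a result in the report that had an interaction test, 65 differed between gallbladder and small intestine in the effect of the gate, 27 with a positive and 38 with a negative difference. The values are the gallbladder log2 fold change minus that of the small intestine, from edgeR. Positive and called under each of the alternatives were Apba1 (14.07), Fxyd6 (13.00), Adamts7 (11.85), Trf (11.67), Cd72 (11.20), Tcerg1l (10.48), Spdef (9.28), Lgr5 (8.50), Nrep (8.28), Ret (6.87), Ascl2 (6.75), Cd79b (6.0) and Tas1r3 (3.54). Negative and called under each were Anxa10 (-11.80), Mx2 (-8.63), Mx1 (-8.43), Il22ra1 (-6.0), Tnfaip3 (-5.11), P2ry1 (-5.00), Gnat3 (-4.92), Basp1 (-4.60), S100a11 (-3.96), Tmem176a (-3.64), Zfp36 (-3.28), Tmem176b (-2.82), Gprc5c (-2.77), Junb (-2.49), Oas1a (-2.49), Dpp4 (-2.46), Oasl2 (-2.29), Slc2a2 (-2.22), Prom1 (-1.98), Mgam (-1.78), Slc4a4 (-1.70), Gabbr1 (-1.62) and Abcc3 (-1.32), which makes 36 genes of both signs.

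For the other 29 genes the difference passed in the chosen fit and missed the threshold under at least 1 alternative. Positive were Gsg1l (16.54), Nrg3 (11.40), Tnfrsf8 (10.63), Tlr9 (9.29), Ctnna3 (7.02), Stxbp5l (6.29), Dpysl3 (4.69), Ffar3 (2.86), Rnf43 (2.41), Kctd12 (1.65), Mgst2 (1.53), Hnf4a (1.44), Egr1 (1.34) and Il13ra1 (1.23). Negative were Slc18a3 (-12.33), Apol9b (-8.99), Ppfia2 (-8.75), Csf1r (-8.45), Cst6 (-7.28), H2-Q7 (-6.79), Fabp1 (-4.45), Sema5b (-3.77), Abcg8 (-3.54), Creb3l3 (-3.12), Krt23 (-3.06), H2-DMb1 (-2.47), Ddc (-1.79), Pla2g4a (-1.35) and Ptpn6 (-0.96).

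By camera 8 gene lists differed between tissues, none with an estimated correlation. Adjusted p was 0.0127 for bile acid and biliary transport, 0.00126 for goblet and interferon response and 0.0251 for Paneth. It was 5.86e-09 for enteroendocrine, 0.000576 for stem and hepatocyte and 0.0276 for proliferation. Genes such as Chgb had little to lose in GB-neg 2 and 3, so for them the gate effect need not differ. Of 100 splits, 54 gave at least 8 lists (highest other 15), so chance is not excluded.

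For genes, 2 of 100 splits, the real one included, gave at least 1536 interaction calls (median of the others 0). The other called 5782 and exchanges the tissue labels within a gate, so it measures the tissue difference. Splits that mix tissues break it too, so chance is not decided. For shared genes, 1 of 100 splits, the real one, gave 2152 (highest other 191). Mixing gates removes the gate effect, so this does not test sharing. The comparisons of 3 with 3 libraries allow 10 splits, too few for a share under 0.05. The real split alone, 1 of 10, called the most genes in the small intestine (4529, highest other 0), the gallbladder (4456 and 0), the IL-25+ groups (3938 and 0) and the IL-25- groups (4099 and 1). For lists, the number of splits with as many as the real one was 1 in the small intestine (16, highest other 12), 2 in the gallbladder (14, highest other 16), 2 between the IL-25+ groups (9, highest other 9) and 3 between the IL-25- groups (13, highest other 13).

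Intestinal transcripts in GB-neg 1 stood at 5.48% of their SI-neg 3 level over 23 enterocyte genes. A small share of reads passed between all libraries alike is argued against, since the highest median in the other 5 gallbladder libraries was 0.328%. Transfer in the direction of GB-neg 1 alone is argued against too, since the ratio of SI-neg 3 to GB-neg 1 over 58 gallbladder genes was nearly constant, with an SD of 0.454 on the log2 scale, against at least 1.18 for the other gallbladder libraries. The profile in GB-neg 1 may come from SI-neg 3, since the SD of the log2 ratio over 112 intestinal genes was 0.222 there and 0.841 or more for the other 5 small intestine libraries. Exchange of index reads between the libraries and mixing of cells or RNA both stay open, and no biological explanation was tested.

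Enterocyte transcripts in small intestine IL-25+ libraries stood at a median of 34.4, 33.3 and 24.3% of their IL-25- level in SI-pos 1 to 3, with Anpep at 1760 against 5670 CPM, Apoa1 at 946 against 3060 and Sis at 644 against 2160. Carry-over alike from each IL-25- cell type is argued against, since goblet and enteroendocrine medians reached at most 2.26% and Paneth medians 1.17, 0.806 and 5.12%. Selective carry-over of enterocytes or their RNA may contribute. Near-equal shares over genes (interquartile range at most 0.402 on the log2 scale, 1.2 to 1.54 for all 3327 abundant genes) do not decide it. MHC class II genes had medians of 29, 26.7 and 22.6% over 3 genes, so their level in small intestine IL-25+ cells, and with it the difference from gallbladder IL-25+ cells, may have the same source, while Fabp1, at 6894 against 761 CPM, stands apart. The gate on red fluorescence would remove enterocytes. Expression at a common fraction by IL-25+ cells would also give equal shares, was not tested and stays open.

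Gallbladder identity transcripts in gallbladder IL-25+ libraries stood at a median of 15, 18.3 and 14.1% of their IL-25- level over 14 genes. Carry-over alike from all IL-25- cells at that share is argued against, since 60 of 2832 genes abundant in each IL-25- library lay under 10% in all 3 IL-25+ libraries. The lowest share of any of these genes was 0.641, 0.737 and 1.7% in GB-pos 1 to 3, with upper 95% counting limits down to 0.864, 1.24 and 1.85%, so a smaller share carried over alike is not excluded. No biological explanation was tested.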

How the results depend on the processing

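Leaving out the 2 libraries that share transcripts, the 2 gallbladder libraries numbered 2, or the mitochondrial genes was chosen after the data had been seen, and the other alternatives were planned.

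Results were named mostly for being called (461 of 467). Of the 461, 341 kept direction and call in each of 23 alternatives that could be fitted. The number of called results that lost the call was 9 of 461 with RLE size factors, 4 of 453 with DESeq2, 37 of 461 with limma-voom, 39 of 461 without the low-count filter, 30 of 461 without the libraries that share transcripts and 61 of 461 without the gallbladder libraries numbered 2. It was 15 to 44 of 461 without a single library. A single result passed the test in the opposite direction: Sucnr1 between the IL-25- groups was -0.14 with all libraries and ranged from -0.71 to 7.2 without a single library, with 7.2 (adjusted p = 0.043) without SI-neg 1. All 59 counts of Sucnr1 in the IL-25- small intestine came from SI-neg 1. Without passing in any fit, Il25 between the IL-25- groups changed sign, from 2.99 to -0.72 without GB-neg 1, as did its interaction (-3.61 to 0.12), and Sucnr1 in the gallbladder went from -0.75 to 0.07 without the gallbladder libraries numbered 2.

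The number of genes called stayed within 1.5 times its value except for 6837 in the small intestine with limma-voom (4529 with edgeR) and 2364 for the interaction with DESeq2 (1536 with edgeR), and the cause was not tested. With an estimated correlation, camera called 1 list in place of 16 in the small intestine, 3 in place of 14 in the gallbladder, 1 in place of 9 between the IL-25+ groups, 1 in place of 13 between the IL-25- groups and 0 in place of 8 for the interaction. The cause was not tested.

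Without a single library, calls ranged from 3125 to 4829 in the small intestine, 3609 to 4512 in the gallbladder, 2815 to 4227 between the IL-25+ groups, 3123 to 4304 between the IL-25- groups, 1054 to 1603 for the interaction and 1630 to 2070 for genes shared by both tissues. Lists called ranged over 15 to 17, 13 to 15, 8 to 10, 11 to 14 and 6 to 11 in the 5 comparisons. A group then holds 2 libraries, which are assumed to vary like the rest.

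With the replicate number as a block, the counts were 4254, 4074, 3540, 3796 and 1340, and with the block nested in tissue 4147 and 3975 for the gate comparisons and 1296 for the interaction. The labels do not say that a number marks a shared animal or day. Same-number libraries correlated at 0.078, 0.033 and -0.093 in the small intestine and 0.022, 0.037 and 0.155 in the gallbladder. Not all were best with their own number, and pairing was not used. It stays open, as the libraries highest in Cxcl5 and Lcn2 share a number.

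On simulated counts, 50 genes were changed per fold. Recovery between groups was 2 to 6% at 2-fold, 28 to 32% at 4-fold, 46 to 58% at 8-fold and 58 to 74% at 16-fold. For the interaction it was 0, 10, 48 and 32%. So few changes make the adjustment stricter than in the data.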

Other observations

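The genes of the libraries numbered 2 were chosen after their values had been seen, and no test was run on them.

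Genes of cell types outside the epithelium were low or mixed. T cell genes Cd3e, Cd3g, Cd8a, Gzma and Gzmb were lower in the gallbladder in both gates, with Ccl5 lower among IL-25+ cells as well, and 0 of 11 T cell genes passed with edgeR in either gate comparison or in the interaction. There 0 had an unadjusted p under 0.05, DESeq2 called 0 in each, and limma-voom called 1 in the small intestine and 0 in the others. Without the gallbladder libraries numbered 2, 1 T cell gene was lower among IL-25+ cells and 0 among IL-25- cells. Of 2 B and plasma cell genes, 0 passed in the small intestine, where 1 had an unadjusted p under 0.05 and DESeq2 and limma-voom called 0, and Pou2af1 was higher in the gallbladder in both gates. Without the gallbladder libraries numbered 2, 1 of the 2 was higher among IL-25+ cells. Cd79b was called in the interaction. Of 6 myeloid genes, Adgre1 was higher and Cd14 lower in small intestine IL-25+ cells, though neither was called without SI-neg 3 and GB-neg 1, and Cd68 and Cd14 were higher in gallbladder than in small intestine IL-25- cells. Csf1r was called in the interaction, but 0 of 6 were without the gallbladder libraries numbered 2. Of 4 stromal and endothelial genes, 0 passed in each of the 5 comparisons with edgeR. There 1 had an unadjusted p under 0.05 between the IL-25- groups, where DESeq2 and limma-voom called 1, and limma-voom called 1 in the small intestine.

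Hepatocyte genes Ttr, Serpina1c, Cyp2e1 and Trf were lower in small intestine IL-25+ cells, 4 of 5 tested, and 3 without SI-neg 3 and GB-neg 1. Trf was called in the interaction. Between the IL-25- groups Ttr was higher and Serpina1c and Cyp2e1 were lower in the gallbladder. Of the exon bases of Serpina1c, 31.5% are covered by a gene on the other strand. Ttr stood at 298 ± 159 CPM and the acinar gene Ctrb1 at 317 ± 34.2 CPM in gallbladder IL-25- cells. Of 2 acinar genes, Clps was lower in small intestine IL-25+ cells, Ctrb1 was higher in the gallbladder in both gates, Clps was lower there among IL-25- cells, and 0 passed in the gallbladder or the interaction. With an unadjusted p under 0.05 there were 1 and 0, DESeq2 called 0 in both, and limma-voom called 1 and 0. Among mitochondrial genes mt-Nd1 and mt-Co1 were lower in small intestine IL-25+ cells (0 adjusted over the list alone), mt-Nd1 and mt-Cytb were lower in gallbladder than in small intestine IL-25- cells (0 without SI-neg 3 and GB-neg 1 or without the gallbladder libraries numbered 2), and 0 of 8 passed in the interaction, where 0 had an unadjusted p under 0.05 and DESeq2 and limma-voom called 0.

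The gallbladder libraries numbered 2 held more Cxcl5, Lcn2 and Ltf than any other library. Cxcl5 stood at 48.6 CPM in GB-pos 2 and 613 in GB-neg 2, and at 3.94 or less in the other 10 libraries. Lcn2 stood at 101 and 623 CPM, against 14.7 or less elsewhere, and Ltf at 93.3 and 413 CPM, against 27.6 or less. For Itgam (17.3 and 211 CPM) and Nos2 (3.08 and 23.1 CPM) this held for GB-neg 2 alone, since SI-neg 1 stood at 38.6 and 13.0 CPM, above GB-pos 2. Of the exon bases of Itgam, 68.7% are shared with another annotated gene on the same strand.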
